A study of Mus musculus with 10 samples.

How the data were processed

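Gene expression was measured in 10 mouse kidney samples, 5 from mice given cyclosporin A (CsA) and 5 from mice given its solvent, with 1 array per sample. The labels do not state that every sample came from a separate animal, and p-values measure only the spread between these samples. Per the labels' protocols, kidneys were taken after 7 daily subcutaneous injections, ground frozen, and 200 ng of total RNA from each was amplified with random primers, labelled with biotin and hybridised to the Affymetrix Mouse Gene ST 2.0 array. This array reads each gene with probes spread along the transcript, so it includes transcripts without a poly(A) tail. The deposited values were log2 expression values, 1 per feature and array. RMA, which corrects background, sets arrays to a common distribution and summarises the probes of a feature, and Partek 6.4 were named in the submitters' processing notes, without their order or settings. The annotation version and the genome build were not given in the sources used here. Detection calls, scan dates and slide numbers were not used here. The number of arrays limits the precision of each value.

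Both deposited value tables held 41345 features and were identical, with a largest difference of 0, so they served as 1 source and the planned comparison between them was not run. Of these features, 8874 carried no gene symbol and 19 showed several symbols in the part of the assignment text that was present, which ended at 87 characters. Symbols were updated through the RefSeq gene table of mouse assembly GRCm38.p6, used only for names and gene lengths. RefSeq accessions named 21749 features, gene identifiers 1909 and synonyms 260, and 8553 kept the deposited symbol. Another 14 symbols that a spreadsheet had turned into dates or numbers were taken from the assignment text. Each gene was represented by its feature with the highest mean over the 10 arrays, which left 30889 genes, with no filter on dim features.

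Groups came from the source descriptions of the samples. CsA was compared with vehicle by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariate) on the log2 values, with Benjamini-Hochberg adjustment over all genes tested. A gene was called changed at an adjusted p under 0.05, and changed at least 2-fold where its log2 difference was also 1 or more in size. Differences are CsA minus vehicle on the log2 scale with the standard error (SE) from the moderated variance. Group means are given with the standard deviation (SD). Probes near background or near the top of the scale compress differences, so folds are those of the array scale.

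The test, the naming rule, the alternatives and 40 gene lists for nephron segments, other cell types and tissues, injury and metabolic responses were fixed before the data were examined. The lists held 631 genes, of which 619 were measured. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 38 lists tested. A list needed at least 5 measured genes, which left out the female-biased kidney list, and the sex-linked list served only to check samples. Camera compares a list with all other genes. It was repeated with a correlation estimated for each list, and beside it fry tested whether a list's genes moved, on balance, in 1 direction. Genes named were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, up to 4 called members per list with the smallest adjusted p, and 14 genes fixed in advance. Model or clone names, small RNAs, olfactory receptors and receptor segments were left out of the largest changes. Any other gene named was chosen after its values were seen. Of the genes this rule selected, 2 are not reported here. They enter every count except that of outlying arrays.

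The sex-linked transcripts showed that 2 CsA arrays carried female RNA, which the labels do not mention. After this was seen, fits with only the 8 male arrays and with a term for the 2 female arrays were added, along with centring within 20 bins of gene length. The alternatives fixed in advance were filters at the 25th percentile and the median of mean signal, quantile normalisation again, centring on array medians, eBayes with trend and robust, array weights, the mean of a gene's features, no variance moderation, all features, and leaving out each array in turn.

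The procedure was tested on simulated arrays with the means and SDs of the real genes. With 100 genes changed per size, the comparison of all 10 arrays over 30889 genes recovered 57% of changes of 0.5 log2 and 98% of changes of 1 log2, with 4 false calls among 161. The males-only comparison over 30889 genes recovered 40% and 92%, with 11 false calls among 143. Noise was drawn for each gene on its own, without correlation between genes, so these rates need not hold for the real arrays.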

Results

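Kidney RNA was profiled after 7 days of cyclosporin A, a calcineurin inhibitor used as an immunosuppressant, at 60 mg/kg per day. The 5 CsA samples were compared with 5 samples from mice injected with the solvent, cremophore, called vehicle here. The mice were 10 to 12 weeks old, of C57BL/6 background, and ate chow with 0.05% sodium. Their line carries an inducible deletion of Vhl in Pax8-expressing tubule cells. The labels do not say whether the deletion was induced in these animals, and Vhl differed by 0.00 ± 0.09 (SE) on the log2 scale between the groups (limma adjusted p = 0.993). The series asked which pathways precede the kidney injury that develops under longer dosing. Array medians lay between 5.14 and 5.21 log2 units, and correlations between arrays between 0.976 and 0.989.

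The first principal component held 29.2% of the variance and separated the groups, with CsA between -33.7 and -7.89 and vehicle between 10.1 and 22.1. CsA replicates 1 and 2 carried Xist, the X-inactivation transcript of females, at 9.21 and 9.15, and a mean of 4 Y-linked genes of only 3.90 and 4.03. In the other 8 arrays Xist was at most 4.82 and the Y-linked mean between 6.91 and 7.66. The CsA group thus held RNA of 2 female and 3 male samples, and the vehicle group of 5 male samples. Values for the 8 male arrays, a comparison chosen after this was seen, are given beside those for all 10 as the males-only values. On the first principal component CsA replicates 1 and 2 lay at -25.1 and -33.7, and the male CsA arrays between -12.4 and -7.89. That component may therefore hold sex as well as treatment.

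**Figure D1:**
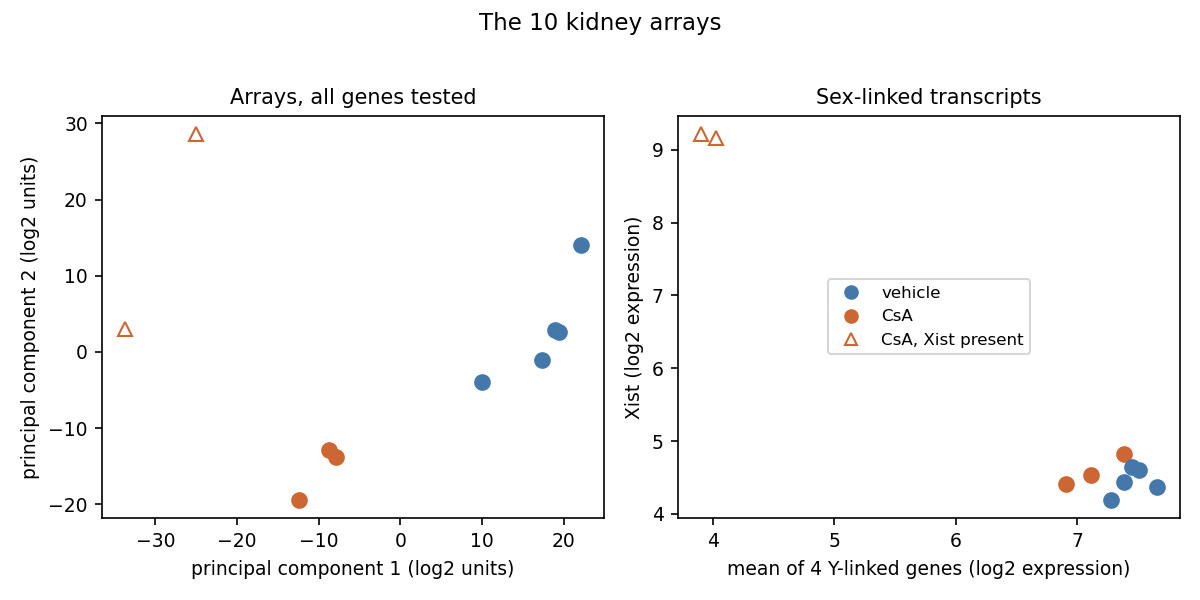
The left panel plots each array on principal components 1 and 2 (log2 units), and the right panel plots Xist against the mean of 4 Y-linked genes (log2 expression). Circles are male arrays and open triangles the 2 CsA arrays with Xist at 9.21 and 9.15, which lie apart from the other 8 arrays on both panels.

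CsA kidneys had less mRNA for several calcium- and magnesium-transporting proteins of the distal nephron and more for renin and for many tubular injury and macrophage genes and some interferon genes. With a correlation between genes estimated for each list, the injury, macrophage and interferon lists missed the threshold (adjusted p = 0.0516, 0.0997 and 0.464). The calcium buffer Calb1 was 4.35-fold lower, the sodium-calcium exchanger Slc8a1 3.70-fold lower, and the injury marker Havcr1 (KIM-1) 3.73-fold higher. The vitamin D binding protein gene Gc rose 6.52-fold, the largest rise among the genes named over all 10 arrays, and 5.41-fold in males only. Slco1a1, an organic anion transporter that male kidneys express, differed by -3.05 ± 0.71 (SE) on the log2 scale over all arrays and by -1.68 in males only, where Calb1 fell more (-2.07). Slco1a1 missed the threshold without CsA replicate 2 (adjusted p = 0.0546) and without vehicle replicates 1, 2, 3 and 4 in turn (0.0541, 0.0645, 0.0678 and 0.0551). Over all 10 arrays, limma called 2003 of 30889 genes changed, 910 higher and 1093 lower, and 57 changed at least 2-fold. In males only, 979 were called, 472 higher and 507 lower, and 40 changed at least 2-fold. Of the 2003 calls, 852 were also called in males only, a comparison that shares 8 of the 10 arrays. Most calls were small, 1472 of them under 0.5 log2 units. The 2 groups did not overlap in 1754 of the called genes and in 9.09% of all genes, against 0.794% by chance. The count of calls fell to 1228 without CsA replicate 2 and to 1220, 1173, 1133 and 1244 without vehicle replicates 1, 2, 3 and 4.

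Calb1 lay at 8.60 ± 0.07 in CsA and 10.71 ± 0.20 in vehicle kidneys (SD, n = 5 each), a difference of -2.12, and -2.07 in males only. Slc8a1, which with Calb1 serves calcium reabsorption, fell from 8.38 ± 0.26 to 6.49 ± 0.19 (limma adjusted p = 6.27e-05). The magnesium channel gene Trpm6 was 2.09-fold lower and Kl, encoding the FGF23 co-receptor klotho, 1.62-fold lower. Of 20 measured genes for distal calcium and magnesium handling, 6 fell and 2 rose over all genes tested, and 9 fell and 2 rose when adjusted over the list alone. The list was lower by camera (adjusted p = 2.24e-05), also with an estimated correlation (adjusted p = 0.0333), and it was the only list to hold there. Its estimated correlation was -0.0145, under the preset 0.01, against 0.14, 0.29 and 0.44 for the injury, macrophage and interferon lists. The cytokine list's estimate (0.0072) was also under the preset, yet its unadjusted camera p rose from 0.0018 to 0.0130. Higher correlation alone thus does not account for the lists that missed. With an estimated correlation, camera also judges its p against the few arrays rather than the many genes, which raises p by itself. In males only, 6 fell and 1 rose, with camera adjusted p = 7.06e-05 and adjusted p = 0.0618 with an estimated correlation, where no list passed. Cyp27b1, which makes active vitamin D, was chosen after its values were seen and was among the genes that rose (log2 difference 1.02 ± 0.27 (SE), adjusted p = 0.0454), and did not pass in males only (1.07, adjusted p = 0.119).

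Some genes of the distal convoluted tubule fell too. Pvalb, the calcium-binding parvalbumin of that segment, was 2.69-fold lower in CsA kidneys, and the kinase gene Wnk1 and the ubiquitin ligase adaptor Klhl3, which regulate the sodium chloride cotransporter, were 1.36-fold and 1.42-fold lower. Of 14 measured genes 5 fell and none rose, with 7 falling when adjusted over the list alone (camera adjusted p = 0.000149; adjusted p = 0.177 with an estimated correlation). In males only 4 fell (camera adjusted p = 8.63e-06; adjusted p = 0.229 with an estimated correlation). The cotransporter gene itself, Slc12a3, differed by -0.32 ± 0.09 (SE) and missed the threshold over all arrays (adjusted p = 0.0669), but passed it in males only (-0.43, adjusted p = 0.0306). In the thick ascending limb list, 4 of 16 genes rose, also 4 when adjusted over the list alone, including Bsnd (1.32-fold) and the calcium-sensing receptor Casr (1.30-fold), with camera adjusted p = 0.0249 and adjusted p = 0.470 with an estimated correlation. In males only limma called none of the 16, with 4 at an unadjusted p under 0.05, and camera gave adjusted p = 0.196. Without CsA replicate 1 or 2 the list also missed the threshold (adjusted p = 0.0595 and 0.0618). Slc12a1 and Egf differed by 0.07 ± 0.08 and -0.07 ± 0.07 (SE), neither past the threshold.

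**Figure D2:**
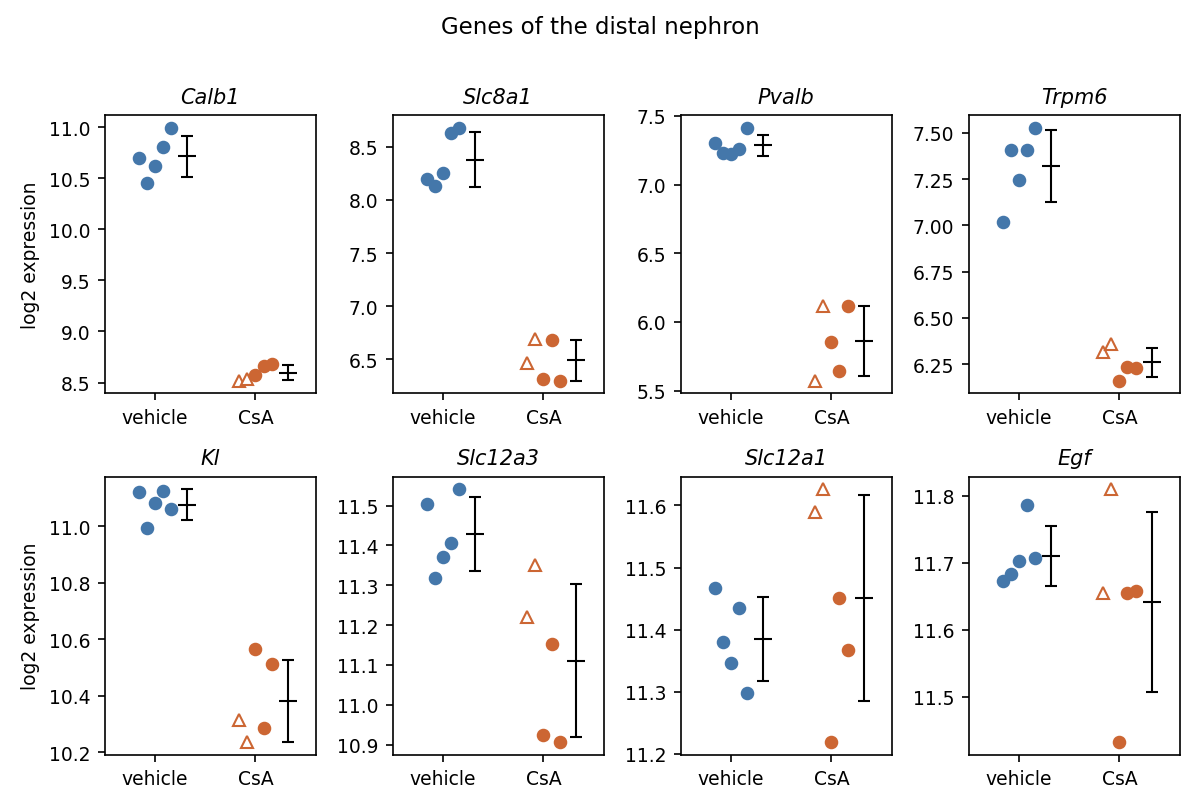
Log2 expression per array of 8 distal nephron genes in vehicle and CsA kidneys, with group mean and SD as bars (n = 5) and open triangles for the 2 female CsA arrays. Calb1, Slc8a1, Pvalb, Trpm6 and Kl lie lower in every CsA array than in every vehicle array, while Slc12a1 and Egf overlap.

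Many tubular injury genes rose. Besides Havcr1, Lcn2 (NGAL, a marker of tubular damage) was 2.41-fold higher, the complement gene C3 2.27-fold and the matrix protein gene Spp1 (osteopontin) 1.89-fold. Havcr1 varied widely among CsA kidneys, at 6.37 ± 1.20 against 4.47 ± 0.42 in vehicle (SD, n = 5). Its log2 difference was 1.90 over all arrays and 2.57 in the males-only comparison, and without CsA replicate 3, which had the highest value (8.31), it was 1.42 and 1.93. Havcr1 missed the threshold without CsA replicate 4 or 5 (adjusted p = 0.0638 and 0.0594) and without vehicle replicate 2, 3, 4 or 5 (0.0712, 0.0684, 0.0623 and 0.0647). Of 23 measured injury genes 13 rose and none fell, with 20 rising when adjusted over the list alone (camera adjusted p = 1.29e-13; adjusted p = 0.0516 with an estimated correlation). In males only 5 rose (camera adjusted p = 1.18e-12; adjusted p = 0.0618 with an estimated correlation).

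Many macrophage genes rose as well. The complement component genes C1qb and C1qc were 1.98-fold and 1.67-fold higher, the macrophage marker Adgre1 1.81-fold and Cd68 1.49-fold. Of 17 macrophage and antigen presentation genes 11 rose, 15 when adjusted over the list alone (camera adjusted p = 1.29e-13; adjusted p = 0.0997 with an estimated correlation), and 8 rose in males only (camera adjusted p = 2.19e-13, and 0.0618 with an estimated correlation). Among interferon response genes, 5 of 17 rose (8 when adjusted over the list alone), led by Irf7 (2.13-fold) and Ifit1 (1.79-fold), with camera adjusted p = 1.09e-05 and adjusted p = 0.464 with an estimated correlation, and 3 rose in males only (camera adjusted p = 3.38e-06, and 0.346 with an estimated correlation). The chemokine genes Cxcl10 and Ccl5 were 2.14-fold and 2.08-fold higher, and 3 of 17 cytokine and chemokine genes rose (4 when adjusted over the list alone), with camera adjusted p = 0.00987 and adjusted p = 0.123 with an estimated correlation. In males only 2 of them rose (camera adjusted p = 0.00480, and 0.214 with an estimated correlation). Limma called no gene of the T cell (14 measured), B cell (10) or neutrophil (9) lists, in which 1, 0 and 1 genes had an unadjusted p under 0.05. Markers of other tissue rose beside the macrophage genes, namely adipocyte genes by camera (adjusted p = 0.0165; adjusted p = 0.567 with an estimated correlation) and, in males only, 3 haemoglobin genes.

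**Figure D3:**
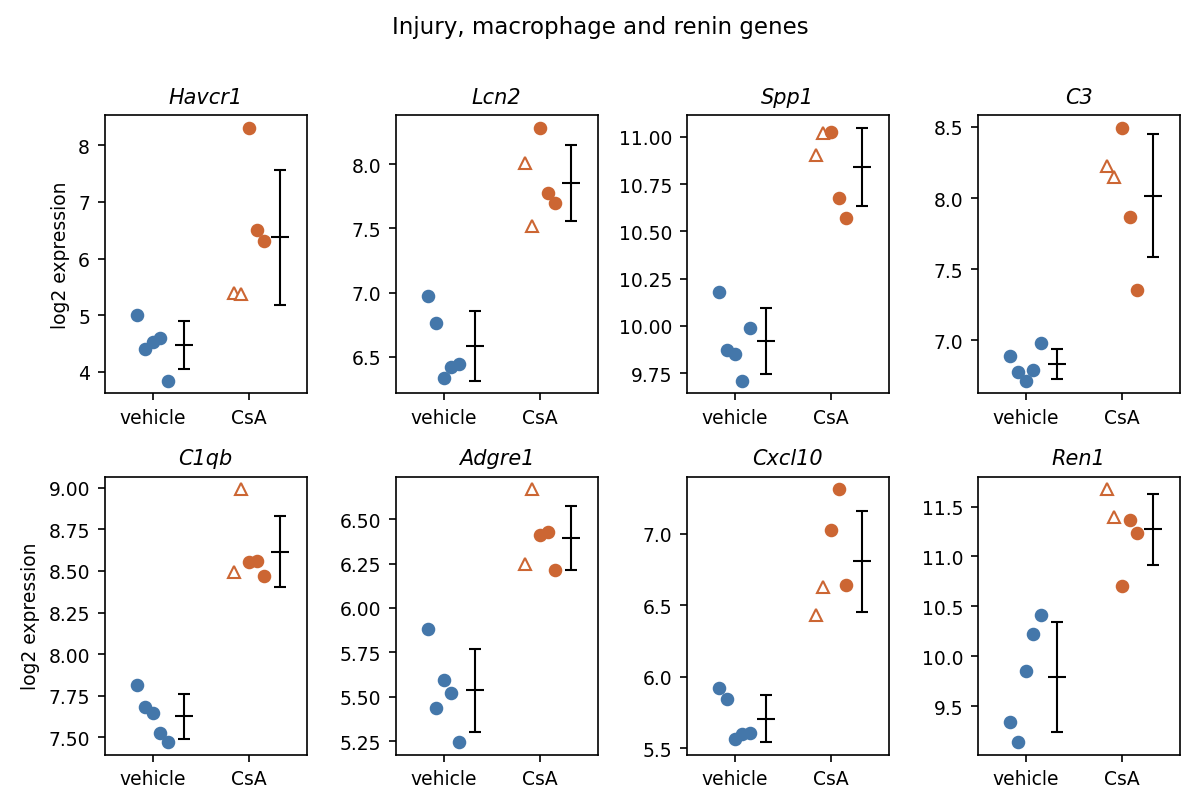
Log2 expression per array of 8 injury, macrophage, chemokine and renin genes in vehicle and CsA kidneys, with group mean and SD as bars (n = 5) and open triangles for the 2 female CsA arrays. All 8 genes lie higher in every CsA array than in every vehicle array, and Havcr1 spreads most within CsA, with an SD of 1.20.

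Renin mRNA (Ren1) was 2.79-fold higher with CsA, at 11.27 ± 0.36 against 9.79 ± 0.55 (SD, n = 5; limma adjusted p = 0.00495), and 1.31 log2 units higher in males only (adjusted p = 0.0426). Akr1b7, another gene of renin-producing cells, was 1.79-fold higher. Ace, which converts angiotensin, fell by 0.58 on the log2 scale, but missed the threshold in males only (-0.44, limma adjusted p = 0.0697). The renin-angiotensin list as a whole had 2 of 19 genes higher and 3 lower (3 and 4 when adjusted over the list alone), and camera did not separate it (adjusted p = 0.672). In males only 2 rose and 1 fell. Of 23 genes for vasoactive mediators limma called none, with 4 at an unadjusted p under 0.05.

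Among the genes of calcineurin, the target of CsA, and of the cyclophilins that bind the drug, 1 of 20 rose and 2 fell, with 4 rising and 6 falling when adjusted over the list alone (camera adjusted p = 0.807), and 1 rising and 2 falling in males only. Ppib was 1.26-fold higher, Ppid 1.44-fold lower and the calcineurin subunit gene Ppp3cc 1.33-fold lower. Cyclophilin A (Ppia) differed by 0.21 ± 0.06 (SE), just outside the threshold (adjusted p = 0.0530), and Rcan1, a calcineurin target gene, by -0.48 ± 0.18 (adjusted p = 0.154). Adjusted over the list alone, both passed (limma adjusted p = 0.0178 and 0.0454). Rcan1 was highest among CsA arrays in CsA replicate 3 (9.72). Without that array its males-only difference moved from -0.33 to -0.62.

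Some genes that differ between male and female mouse kidneys were called, and the 2 female arrays enlarged their differences. Prlr, the prolactin receptor, was 3.33-fold higher, and Slc7a12 3.99-fold higher. In males only Prlr was 1.20 log2 units higher (adjusted p = 0.0201) and Slc7a12 1.62 higher without passing (adjusted p = 0.0751). Of the 3 measured female-biased genes, 2 rose, and 3 when adjusted over the list alone. Of 7 male-biased genes, Slco1a1 alone fell, with 4 falling when adjusted over the list alone (camera adjusted p = 0.000706; adjusted p = 0.490 with an estimated correlation). In males only 3 of the 7 fell, Slco1a1 by 1.68, Cyp7b1 by 0.90 and Cyp2j13 by 0.58 on the log2 scale (camera adjusted p = 0.000237; adjusted p = 0.292 with an estimated correlation). Kap, an androgen-dependent kidney gene, differed by -2.29 ± 1.07 (SE) over all arrays and by -0.14 ± 0.07 in males only, neither past the threshold.

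Metabolic genes moved in both directions. In cholesterol synthesis, 5 of 18 genes rose and 5 fell (7 and 5 when adjusted over the list alone, 1 and 1 in males only), with Fdps 1.52-fold higher and Hmgcs1 1.55-fold lower (camera adjusted p = 0.391). Of 18 oxidative phosphorylation genes, 1 rose and 5 fell (2 and 6 when adjusted over the list alone, 1 and 1 in males only), including Ndufs1 (1.31-fold lower) and Cox4i1 (1.24-fold higher), with camera adjusted p = 0.127. Acadm and Acadl, which begin fatty acid oxidation, were 1.39-fold and 1.25-fold lower, in a list with 1 of 18 genes higher and 2 lower (the same numbers when adjusted over the list alone; camera adjusted p = 0.0707). In males only 1 of the 18 fell and none rose. The transporters Abcg2 and Slc22a2, which carry drugs and organic cations, were 1.45-fold and 1.46-fold lower. In males only Abcg2 passed the threshold (-0.51, limma adjusted p = 0.00764) and Slc22a2 did not (-0.33, limma adjusted p = 0.0923). Of 19 xenobiotic genes 4 fell, 5 when adjusted over the list alone and 1 in males only (camera adjusted p = 0.225, fry adjusted p = 0.0112). In the list for endoplasmic reticulum stress, 3 of 28 genes rose, Asns (2.14-fold), Atf3 (1.38-fold) and Sdf2l1 (1.36-fold), also 3 when adjusted over the list alone and 1 in males only (camera adjusted p = 0.0320; adjusted p = 0.632 with an estimated correlation). In males only camera gave adjusted p = 0.00389, and 0.639 with an estimated correlation. The list missed the threshold without CsA replicate 3 or 4 (adjusted p = 0.103 and 0.178) and without vehicle replicate 1 or 4 (0.0924 and 0.0520). The stress genes Hspa5 and Ddit3 differed by 0.06 ± 0.11 and 0.26 ± 0.09 (SE), neither past the threshold. Of 24 hypoxia genes 2 fell, Egln1 and Ldha (camera adjusted p = 0.0906), with 1 rising and 3 falling when adjusted over the list alone and none called in males only, where 7 had an unadjusted p under 0.05. The hypoxia-induced genes Epo and Vegfa differed by 0.05 ± 0.11 and -0.08 ± 0.07.

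Immediate early genes included rises of Egr1 (1.76-fold) and Fos (1.51-fold) and a fall of Ier3 (1.66-fold lower), 4 of 13 genes higher and 1 lower (5 and 1 when adjusted over the list alone, 1 and 1 in males only; camera adjusted p = 0.0612, fry adjusted p = 0.0220). Of 15 clock genes 2 fell, Nr1d2 and Hlf, also 2 when adjusted over the list alone and 1 in males only (camera adjusted p = 0.0626). In males only camera gave the list adjusted p = 0.00904, and 0.282 with an estimated correlation. Limma called no cell cycle gene of 20, with 6 at an unadjusted p under 0.05 and a median difference of 0.13, although camera called the list higher (adjusted p = 0.0202; adjusted p = 0.464 with an estimated correlation; adjusted p = 0.0756 without CsA replicate 3). In males only limma again called none, with 7 at an unadjusted p under 0.05, and camera gave adjusted p = 0.000787, or 0.207 with an estimated correlation. Adipocyte genes, markers of fat around the organ, were also higher by camera (adjusted p = 0.0165; adjusted p = 0.567 with an estimated correlation), with 1 of 10 genes called, Retn (1.76-fold higher), 2 when adjusted over the list alone and 2 in males only. Their median was 0.26, or 0.67 in males only (camera adjusted p = 5.66e-06 there, and 0.346 with an estimated correlation), and the list missed the threshold without CsA replicate 4 or vehicle replicate 5 (adjusted p = 0.0882 and 0.0540). Of 8 erythroid genes limma called none over all arrays, with 4 at an unadjusted p under 0.05 and 2 higher when adjusted over the list alone, and 3 rose in males only. Camera gave that list adjusted p = 0.391 over all arrays and 0.00877 in males only, or 0.346 there with an estimated correlation. In the proximal tubule list, 1 of 25 genes, Miox, was called, 1.20-fold higher, also 1 when adjusted over the list alone and none in males only (4 at an unadjusted p under 0.05). Limma called no matrix or fibrosis gene of 26, podocyte gene of 11, endothelial gene of 14 or smooth muscle gene of 11, with 5, 1, 7 and 3 at an unadjusted p under 0.05. Adjusted over the list alone, 1 endothelial gene was higher and 2 lower, and in males only 1 endothelial gene, Ehd3, was called lower (-0.46, adjusted p = 0.0249).

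**Figure D4:**
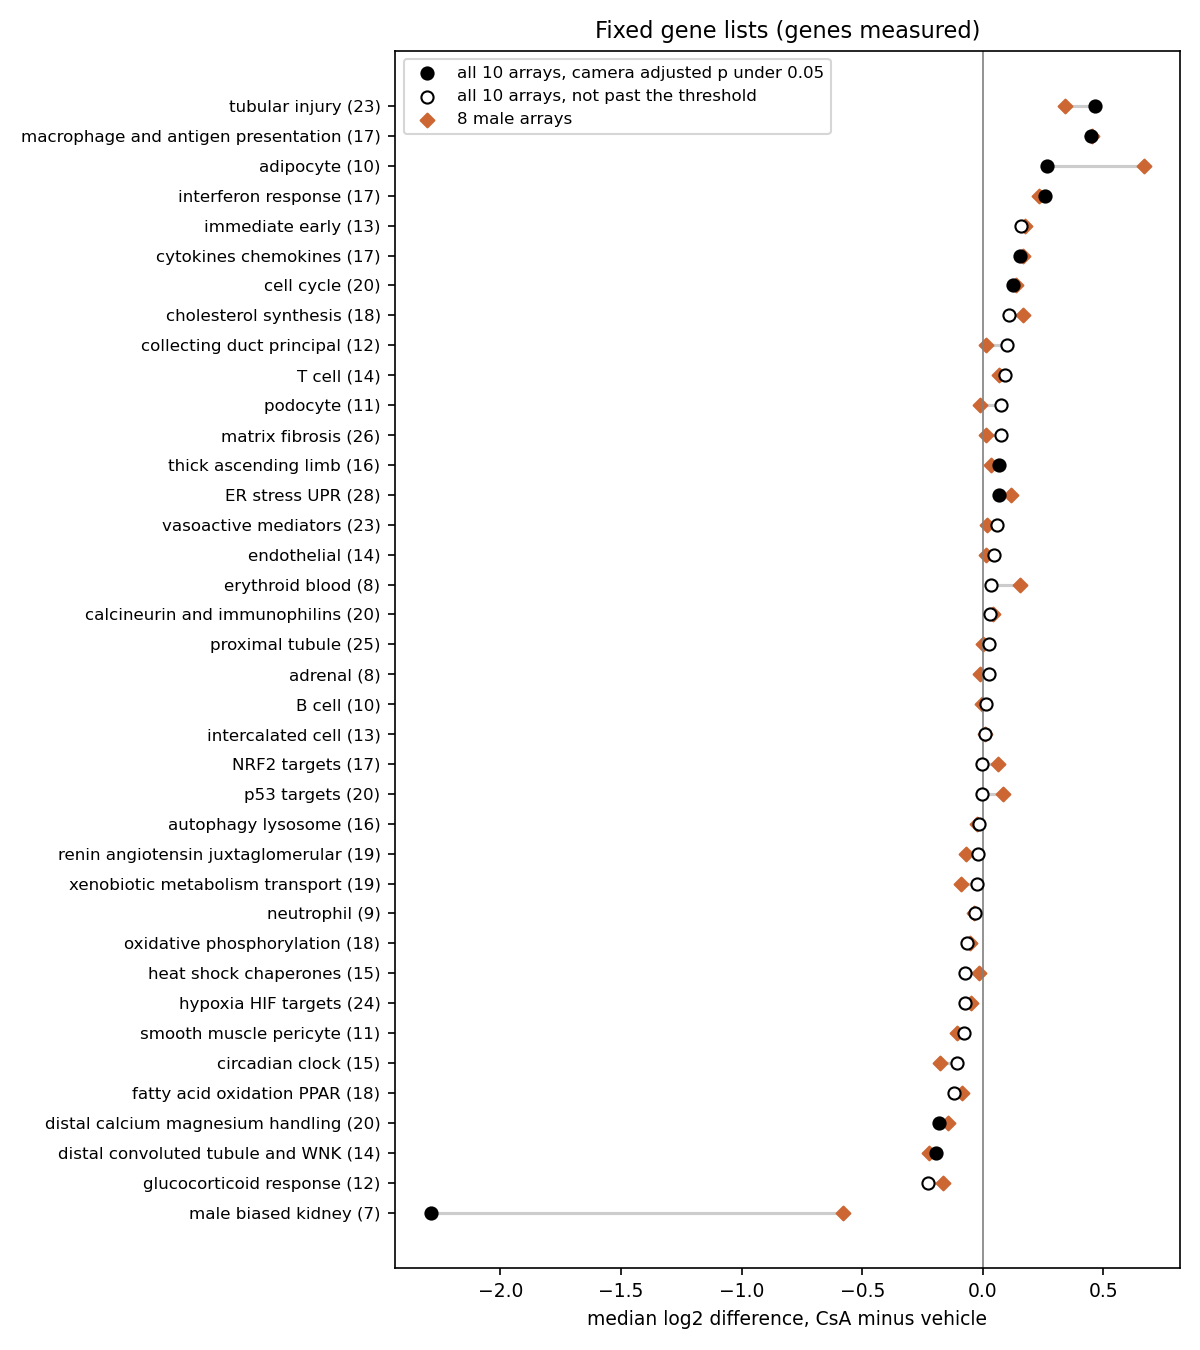
Median log2 difference, CsA minus vehicle, of 38 gene lists over all 10 arrays (circles, filled where camera's adjusted p passed the threshold) and over the 8 male arrays (diamonds), with the number of genes measured in parentheses. Injury and macrophage lists have the highest medians, 0.46 and 0.45 over all arrays, and the male-biased list the lowest, -2.29.

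The other large changes included rises of Wfdc16 (2.68-fold) and the B cell surface protein gene Cd72 (2.29-fold), and falls of Tc2n (3.87-fold lower), Rnf24 (2.59-fold lower), the lipid transporter Mfsd2a (2.36-fold lower), Smcp (2.35-fold lower) and the ether lipid enzyme Agps (2.27-fold lower). Slc22a26, Slc22a19 and Cyp4a12b were 2.42-fold, 2.34-fold and 2.41-fold lower, but they have close relatives, and probes for them may also read those. The 2 female arrays enlarged several of these folds. In males only Tc2n was 2.45-fold, Slc22a26 1.65-fold and Cyp4a12b 1.59-fold lower, and Wfdc16 2.02-fold higher. There Mfsd2a missed the threshold (-1.05, adjusted p = 0.0573), and the other genes of this paragraph passed it.

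Small nucleolar RNA genes, chosen as a class after their values were seen, were higher by a median of 0.49 over 107 genes, 72 of them called higher and none lower. Of 81 ribosomal protein genes 38 were called higher and none lower, at a median of 0.25. In males only, 50 small nucleolar RNA genes were higher and none lower, and 24 ribosomal protein genes were higher and 1 lower. Both medians stayed above 0 under each scaling tried, at 0.46 to 0.51 and 0.21 to 0.25, and at 0.37 and 0.19 after the length trend of other genes was removed. Sample numbers in the titles ran from 21 to 25 in CsA and from 26 to 30 in vehicle. Any handling that followed these numbers cannot be told apart from treatment for any gene described.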

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

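The distal tubule and small RNA patterns below were picked after the results were seen, as was the males-only comparison. Of the tests of these patterns, only that of genes under 1 kb had its limits written before it was run. The count of called genes was set against other divisions of the same arrays. Of 100 divisions of the 10 arrays into 5 and 5, drawn from 126, only the real 1 reached 2003 calls, and the highest of the others called 1 gene. Of the 56 divisions of the 8 male arrays into 3 and 5, only the real 1 reached 979 calls, and the highest other again called 1. Chance division of the arrays is therefore unlikely for both counts but not excluded, since only 100 and 56 divisions were compared. The 8 male arrays are among the 10, so the counts are not separate evidence. Neither count says anything about handling that followed the groups.

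Calb1, Slc8a1, Trpm6 and Pvalb, picked for their large falls, fell by a mean of 1.62 log2 units. Fewer distal convoluted tubule cells would lower the other genes of that segment as well. The 13 other genes of the segment's list, fixed in advance, had a median difference of -0.17, a lower quartile of -0.32 and a largest fall of 0.51, and Slc12a3, the segment's sodium chloride cotransporter, differed by -0.32 ± 0.09 (SE). The smaller fall of Slc12a3 argues against loss of cells throughout the distal convoluted tubule as the whole cause of so large a fall. It does so only weakly, since Slc12a3 was bright (11.43 in vehicle) and the array may compress its fall. The 13 genes as a set cannot bound such a loss. Several of them are also expressed in other cells, and the 4 genes were picked for falling most. Slc12a3 fell by 0.43 in males only, so some loss stays open. Loss limited to a part of the segment, or of other distal nephron cells, was not tested. The female samples do not account for the fall of the 4 genes, since they differed by -1.64 ± 0.08 (SE) in males only. An effect of CsA on the expression of these genes stays an untested hypothesis, and any handling that followed the sample numbers cannot be told apart from it.

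Of 107 small nucleolar RNA genes 72 were called higher, with a median of 0.49 over the class, and of 81 ribosomal protein genes 38, with a median of 0.25. The female samples do not account for this, since the medians in males only were 0.45 and 0.25. Removing a trend with gene length left most of the small nucleolar RNA rise, but the removal was coarse. Its shortest bin gave 1 value per array to all genes up to 1262 bases, so a steeper trend among the shortest genes was not removed. After the length trend of other genes with a mean log2 value of 6 or more was removed from each array, a median of 0.37 ± 0.05 (SE between arrays) was left of 0.49, over the 106 genes with a length. Centring all genes within 20 length bins left 0.46, with 70 of 107 still called higher. For ribosomal protein genes the same 2 corrections left 0.19 ± 0.04 of 0.26 and 0.21, with 32 of 81 called higher. That was also most of the rise, but the SE is large against so small a rise. A larger part going with length therefore stays open for these genes. How much of either rise goes with length cannot be told, since 476 other genes under 1 kb had a median of 0.11 and an upper quartile of 0.30. A difference in RNA or array handling may also produce such a rise, and it cannot be told apart from treatment, because 0 arrays were out of group order in the sample numbers. An effect of CsA itself stays an untested hypothesis, and GC content was not tested because no genome sequence was used.

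Single arrays far from the rest of their group were found in 7 of 218 groups tested (3.21%), against the 1 in 20 that chance gives. Of the 113 named genes 91 were called, a choice that favours small spread within groups, and all share the same arrays. The rate therefore does not bear on the quality of the arrays. In CsA replicate 3, Rcan1 was 9.72, against 8.97 for the nearest array. Ddit3 was low in vehicle replicate 4, at 6.04, and Akr1b7 in vehicle replicate 2, at 3.96. Ppp3cc and Cldn19 were low in vehicle replicate 5, at 7.19 and 8.33. Cyp51 was low in CsA replicate 4, at 8.36. C1qb was high in CsA replicate 2, at 8.99. Among the 8874 features without a gene symbol, which enter no comparison above, 198 were called, 63 higher and 135 lower with CsA, 18 of them at least 2-fold.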

How the results depend on the processing

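The males-only fit, the female term and the length bins were chosen after the data were seen. No result changed direction past a threshold. Over 113 named genes and 2367 alternative values, 2010 stayed on their side of the threshold, 333 lost it and 24 gained it. The 27 lists not called over all arrays passed in 22 of 590 alternative values. Calls numbered 1718 to 2765 under the other settings, leaving aside the fits named next and arrays left out. Called genes numbered 979 in males only (472 higher, 507 lower) and 1008 with the female term (500, 508), where fewer CsA samples inform the difference. Both fits give each gene the same difference, since both female arrays were in CsA, and only its estimated spread differs. The thick ascending limb list then had adjusted p = 0.196 and 0.167. Above the median of mean signal, with fewer genes tested, 3283 were called (1475 higher, 1808 lower) and 6 lists, without adipocyte (0.102), cell cycle (0.278), cytokines (0.0631), endoplasmic reticulum stress (0.100) and thick ascending limb (0.0946). Above the 25th percentile, endoplasmic reticulum stress had 0.0764 and thick ascending limb 0.0559. The cause was not tested. With an estimated correlation 1 list passed, and the other values were adipocyte 0.567, cell cycle 0.464, cytokines 0.123, distal convoluted tubule 0.177, endoplasmic reticulum stress 0.632, interferon 0.464, macrophage 0.0997, male-biased 0.490, thick ascending limb 0.470 and tubular injury 0.0516. By fry, adipocyte had 0.205, cell cycle 0.0530, endoplasmic reticulum stress 0.159 and male-biased 0.138, while 2 lists that camera did not call passed, xenobiotic (0.0112, lower) and immediate early (0.0220, higher).

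Leaving out each array in turn gave 1133 (without vehicle replicate 3) to 1926 calls, with 1228 without CsA replicate 2 and 1220, 1173 and 1244 without vehicle replicates 1, 2 and 4 (559 to 882 higher, 574 to 1044 lower), 40 to 83 changed at least 2-fold and 10 to 13 lists. Adjusted p ranged from 8.93e-05 to 0.0882 for adipocyte, 0.00494 to 0.0756 for cell cycle, 0.00285 to 0.0303 for cytokines, 1.64e-05 to 6.19e-05 for distal calcium and magnesium, 4.04e-05 to 0.00195 for distal convoluted tubule, 0.00268 to 0.178 for endoplasmic reticulum stress, 1.15e-07 to 0.000219 for interferon, 2.45e-14 to 1.32e-11 for macrophage, 3.94e-05 to 0.00618 for male-biased, 0.00700 to 0.0618 for thick ascending limb and 5.06e-15 to 5.66e-12 for tubular injury. Adipocyte missed the threshold without CsA replicate 4 or vehicle replicate 5 (0.0540), cell cycle without CsA replicate 3, thick ascending limb without CsA replicate 1 (0.0595) or 2, and endoplasmic reticulum stress without CsA replicate 3 (0.103) or 4 or vehicle replicate 1 (0.0924) or 4 (0.0520). Lists were not tested without variance moderation, and the 2 deposited tables were identical. Array signal near background limits dim genes, for which no detection calls were used.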

Other observations

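The values in this part come from lists fixed in advance, and only their males-only counts were chosen after the data were seen. In the lysosome and autophagy list, 2 of 16 genes rose and 2 fell, the lysosomal enzymes Hexa and Ctsd being 1.28-fold and 1.18-fold higher and Becn1 and Lamp2 1.25-fold and 1.17-fold lower (limma camera adjusted p = 0.476). In males only limma called none of them, with 4 at an unadjusted p under 0.05. Atp6v1b1, a proton pump subunit of intercalated cells, was 1.38-fold higher and the only called gene of 13 in its list, also in males only (camera adjusted p = 0.515). Fxyd4 of principal cells was 1.35-fold higher, the only called gene of 12 (camera adjusted p = 0.184), and in males only limma called none, with 4 at an unadjusted p under 0.05. Of 8 adrenal genes Akr1b7 alone was called (camera adjusted p = 0.339), and the renin list holds it too.

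Among targets of NRF2, the antioxidant regulator, 2 of 17 genes rose and 2 fell, with the efflux pump gene Abcc4 1.65-fold higher and Me1 1.68-fold lower (camera adjusted p = 0.612). In males only 1 rose and 1 fell. Among glucocorticoid response genes 1 of 12 rose and 2 fell, Klf9 being 1.32-fold and Errfi1 1.29-fold lower (camera adjusted p = 0.339), and in males only limma called none, with 6 at an unadjusted p under 0.05. The mitochondrial chaperone gene Hspd1 was 1.40-fold lower, the only called gene of 15 in the heat shock list, also in males only (camera adjusted p = 0.310). Ccng1 was 1.40-fold lower and the only called gene of 20 p53 targets (camera adjusted p = 0.656), none of which limma called in males only, with 6 at an unadjusted p under 0.05.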
